A study of Mus musculus with 2 samples.

How the data were processed

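RNA from mouse monocyte-derived dendritic cells (moDCs) was measured on 2 two-colour microarrays of 60-base probes. Per the labels, monocytes of C57BL/6 mice were cultured for 24 h with 20 ng/ml GM-CSF and 10% serum, either alone (control moDCs) or with 20 ng/ml IL-4. The cultures held about 90% moDCs, and CD11c-positive cells were then selected with antibody-coated magnetic beads. RNA was amplified with aminoallyl-modified UTP and coupled to Cy3 or Cy5. Each array carried both kinds of cell. On array 1 the IL-4 sample was in Cy3 and the control in Cy5, and on array 2 the dyes were exchanged. Both arrays lay on the same slide. The labels call the arrays replicates 1 and 2 but do not say whether the cells came from separate cultures or animals. The p-values and SDs measure the spread between the 2 arrays, which may be technical. That spread also holds the dye bias of single probes, since the dyes were exchanged between the arrays and the main test had no dye term. The names of the scanner output carry the abbreviation LPS, which commonly stands for lipopolysaccharide, a stimulus of dendritic cells. The labels name only GM-CSF and IL-4, and whether the cultures also received lipopolysaccharide is not given in the sources used here. This limits what every ratio of IL-4 over control compares.

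Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1, and probe positions refer to the mouse build mm9. The deposited scanner tables give, for each spot and dye, the mean pixel intensity and the median intensity of the local background, neither background-subtracted nor dye-normalised. They also give a processed intensity per dye, which, per the file headers, was background-subtracted, detrended and dye-normalised, and a log10 ratio of processed Cy5 to processed Cy3. The authors also deposited 1 table for the whole series with a log2 ratio per spot. Its direction was not stated. Against the processed intensities of bright spots, that table correlated at r = 0.991 on array 1 and 0.992 on array 2 as IL-4 over control, with slopes of 0.971 and 0.953. How its values were background-corrected and normalised is not given in the sources used here.

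The main values were computed from the mean spot intensities. Background was corrected with the normexp method (offset 50), and the log2 ratio of Cy5 to Cy3 was normalised by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots of the same probe were averaged. The sign of array 1 was then turned, so that every ratio below reads IL-4 over control. Of 39429 probes, 23530 were kept. A probe had to be well above background on both arrays in the IL-4 channel, or on both arrays in the control channel, and free of the non-uniformity flag of the scanner software. The background rule removed 15666 probes (39.7%) and the flag 233. A gene was read by its probe with the highest mean log2 intensity, which left 18749 gene names, of which 12886 were gene symbols. A reference list of mouse genes for the assembly GRCm38.p6 was used for names only. It paired 13439 of the features with a current symbol, and 758 of these differ from the symbol on the array. A ratio is given as a bound ("at least") where neither array was well above background in the lower group.

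Offsets and loess pull ratios of dim spots towards 0, and each dye has its own response to a probe, which the exchange of dyes is meant to cancel in the mean of both arrays. Array number limits the precision: with 2 ratios per gene, 1 residual degree of freedom remains, and limma's moderated variance (prior SD 0.679, prior degrees of freedom 4.15) carries most of the test. Genes were tested with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Genes at least 2-fold higher or lower on both arrays were counted as well, without a test. The count expected if the arrays were independent is the product of the counts on each array divided by the number of genes. Values are given as the mean log2 ratio ± SD of the 2 arrays.

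Before the data were examined, 33 gene lists with 882 entries were fixed (pathways, functions and markers of dendritic and other cells), of which 773 entries could be tested. The lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists, beside camera with an estimated correlation and fry. Members were also adjusted over the list alone with limma's p-values. The named genes also followed a rule fixed in advance. It took 12 genes per direction, ranked by smallest unadjusted p where fewer passed the threshold and leaving out names that are accessions, clones or predicted-gene numbers (RIKEN, LOC and Gm names), up to 4 members with the smallest p of a described list, and 24 genes chosen by name. Gene families given under the closing observations were chosen after their values were seen.

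The procedure was tested on simulated data with the spread of these arrays and known changes among the 18749 genes. Of genes changed 2-, 4-, 8-, 16-, 32- and 64-fold, the limma test recovered 0%, 0.882%, 11.8%, 43.8%, 72.1% and 82.7%, and 82 of the 767 calls over 10 draws were false. For lists shifted by 0.5 on the log2 scale, camera with the preset correlation recovered 86 of 100 and called 1 of 230 unmoved lists, whereas camera with an estimated correlation and fry recovered 0 of 100 each. The simulated genes were drawn independently of each other, without dye bias or a negative correlation between the arrays. The low count of false list calls therefore need not hold for these data, where genes may be correlated.

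The alternatives tried were no background correction, normexp with offset 16, the processed intensities, median centring in place of loess, quantile normalisation of the average intensity, no filter and a strict filter on dim probes, the mean of a gene's probes, the deposited series table, other fold thresholds, other adjusted p thresholds, other variance models, separate-channel fits with and without a dye term, a test per probe, a rank-based camera and 1 array at a time. An added alternative, chosen after seeing the data, removed each array's linear trend with the numbers of A, C and G in the probe. Control probes were left out of the comparison.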

Results

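The data comprised 2 arrays, each setting moDCs cultured with GM-CSF and IL-4 against moDCs cultured with GM-CSF alone, with the dyes exchanged between arrays (n = 2 ratios per gene). The median spot signal was 256 for IL-4 (Cy3) and 109 for control (Cy5) on array 1, and 97.2 for IL-4 (Cy5) and 247 for control (Cy3) on array 2, over median backgrounds of 37 to 39. Spots well above background made up 66.0% and 66.1% of the IL-4 and control spots on array 1, and 65.2% and 58.7% on array 2. Saturated spots numbered 0 on each array. Log2 ratios of the 18749 tested genes had an SD of 0.889 on array 1 and 0.730 on array 2, with medians of 0.05 and -0.02.

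The comparison of IL-4 moDCs with control moDCs addresses how IL-4 shapes dendritic cells that license Th2 responses, the subject named in the series title. IL-4 moDCs had higher signals for markers of alternative activation, the IL-4 and STAT6 programme known from macrophages. Chi3l3 (now Chil3, the chitinase-like protein Ym1) had a log2 ratio of 6.36 ± 2.56 (SD, n = 2), Retnla (the secreted protein Fizz1) 4.75 ± 1.82, the scavenger receptor Cd36 4.58 ± 0.84 and Arg1 (arginase 1) 3.91 ± 0.27, or 15.0-fold. Ly6i, Ly6a and Ly6c1, which encode surface proteins of the Ly6 family, were lower at -4.16 ± 0.03, -3.46 ± 0.54 and -3.32 ± 0.83. The formyl peptide receptor Fpr1 was lower at -3.10 ± 0.27. Of all tested genes, 182 were at least 2-fold higher and 242 at least 2-fold lower on both arrays.

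The gene test itself called none of these. With limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, the smallest adjusted p being 0.502. At an unadjusted p under 0.05, limma had 238 genes higher and 291 lower, 529 in all against 937 expected by chance. In a limma variance model with an intensity trend and a robust prior, the smallest adjusted p was instead 0.0522. The distance from the threshold thus depends on the variance model. A separate-channel limma fit with a dye term called 4 genes higher (Rbp4, Ear11, Cd36 and Ear10) and 0 lower. With that term, the residual is the difference in mean spot intensity between the arrays. Its p-values therefore do not measure the spread of the IL-4 over control ratio. A separate-channel fit without that term called 0 in each direction. After removal of the trend with probe bases, a step chosen after seeing the data, limma called 12 genes higher, among them Arg1, Cd36, Chi3l4, Flt1 and Rbp4, and 1 lower, Ly6i. A change to median centring gave 3 genes higher (Chi3l3, Ear11 and Rbp4), and the processed intensities gave 1, Rbp4.

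The arrays ran in opposite directions for most genes. Across the 18749 genes, which are not independent replicates, the IL-4 over control ratios of the 2 arrays had a Pearson r of -0.285 and a Spearman rho of -0.360, and 36.5% of genes had the same sign on both. The 182 and 242 genes at least 2-fold on both arrays compare with 115 and 134 expected if the arrays were independent, while 902 were at least 2-fold higher on array 1 and lower on array 2, and 197 the reverse. Fewer genes than expected ran the same way at 1.5-fold, with 431 higher and 551 lower against 614 and 725. At 4-fold, 54 genes were higher and 35 lower on both arrays, with 3.40 and 1.48 expected if independent and 141 and 0 in opposite directions. At 16-fold, 8 genes were higher and 1, Ly6i, lower on both, and 0 were in opposite directions. Median centring gave 102 genes at least 2-fold higher and 210 at least 2-fold lower on both arrays.

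**Figure D1:**
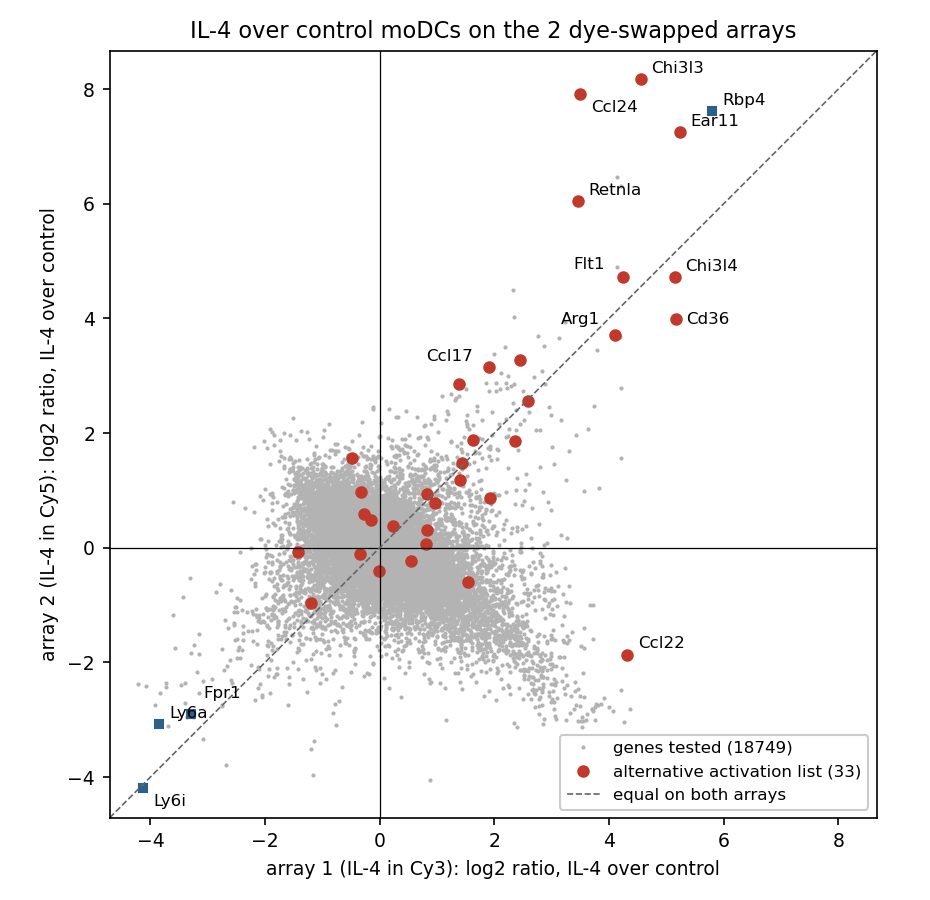
Log2 ratio of IL-4 over control moDCs on array 1 (horizontal) and array 2 (vertical) for the 18749 tested genes (grey), with the 33 tested alternative activation genes in red, other labelled genes as blue squares and the line of equal ratios dashed. Most genes have opposite signs on the 2 arrays (r = -0.285), while Arg1, Cd36, Retnla, Chi3l3 and Ly6i have the same sign on both arrays and Ccl22 does not.

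Of the genes that the limma test ranked first in the higher direction, Rbp4, the retinol-binding protein, had log2 ratios of 5.80 and 7.62 on arrays 1 and 2 (mean 6.71 ± 1.29). Its control signal was well above background on 1 array. Its probe maps to chromosome 19 from 38191120 to 38191179 in mm9. Chi3l4 (now Chil4, the chitinase-like protein Ym2; chromosome 3, 106006584 to 106006643) had a mean of 4.93 ± 0.31, and Ear11, a ribonuclease gene of the eosinophil-associated family (chromosome 14, 51875064 to 51875123), 6.24 ± 1.41. Its relatives Ear2, Ear10 and Ear12 had means of 4.51 ± 0.54, 5.30 ± 1.65 and 3.62 ± 0.24. The Ear and chitinase-like genes have near-identical copies that probes can share, so the single values are uncertain. The probes of Ear2 (44681119 to 44681178) and Ear12 (44680899 to 44680958) lie close together on chromosome 14, and Ear12 was paired with no current symbol. Ear2 and Ear12 may therefore be the same gene. Flt1, a receptor for vascular endothelial growth factor, had 4.48 ± 0.33, but its other probe gave 1.32. Cd36 lies on chromosome 5 (17288600 to 17288659) and Arg1 on chromosome 10 (24636194 to 24636253). Chst7, a sulfotransferase gene, had 3.88 ± 0.22. Bex6 had 3.93 ± 0.36 with 1.12 from its other probe, and the adhesion molecule gene Vcam1 3.59 ± 0.49 with 0.75 from its other probe. None of these passed adjustment over all genes.

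In the lower direction, the first-ranked gene was Ly6i (chromosome 15, 74810484 to 74810543) with -4.14 and -4.19 on the 2 arrays. The paired immunoglobulin-like receptor genes Pilrb2, Pilra and Pilrb1, neighbours on chromosome 5, had means of -3.39 ± 0.41, -3.16 ± 0.29 and -3.10 ± 0.21. The 4 Pilra probes ranged from -3.39 to -0.99, and the other Pilrb2 probe gave -2.85. Of Ly6c1, the other probe gave -2.59. As for the Ly6 genes, their sequences are alike and the single values are uncertain. Ifitm1, an interferon-induced transmembrane protein gene, had -3.21 ± 0.17. The junctional adhesion molecule gene F11r had -3.05 ± 0.48, and Emr4 (now Adgre4), an adhesion receptor of the F4/80 family, -3.24 ± 0.78. Dusp6, a phosphatase that inactivates ERK, had -2.76 ± 0.02, and the purine receptor gene P2ry13 -2.74 on both arrays. Adjusted p-values of these genes in limma lay between 0.502 and 0.705.

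Genes chosen in advance went several ways. Mrc1, the mannose receptor, had 2.11 ± 0.36, and Pdcd1lg2, which encodes the PD-1 ligand PD-L2, 1.76 ± 0.18. The chemokine genes Ccl24 and Ccl17 had 5.71 ± 3.13 and 2.53 ± 0.88. Ccl22 had opposite ratios, 4.32 on array 1 and -1.87 on array 2. Il6 had 1.35 ± 0.73 and Nos2, the inducible nitric oxide synthase, 1.21 ± 0.48, both higher on both arrays. Il1b had -1.93 ± 1.65 and Tnf -0.81 ± 0.75, both lower on both arrays. The scanner output is named with the abbreviation LPS, which the labels do not explain, so whether these cytokine genes and the chemokine genes were read in cells that also received lipopolysaccharide is not given in the sources used here. Irf4 had -0.75 ± 0.96, Il12b -0.58 ± 1.05 and Il23a -0.40 ± 0.58. The co-stimulatory genes Cd40 and Cd80 had 0.51 ± 0.30 and 0.27 ± 0.34, but the other Cd80 probe gave -0.23. For the IL-4 receptor chain Il4ra and the cytokine signalling inhibitors Socs1 and Cish, the 2 arrays had opposite signs, with means of 0.17 ± 0.45, 0.33 ± 0.91 and 0.16 ± 0.55. The sign of the Il4ra and Cish means turned with median centring. Cd209a, the gene of the lectin DC-SIGN, had -0.16 ± 0.03 and 0.09 from its other probe. With limma, 0 of the 21 tested genes chosen by name passed adjustment over all genes, and 10 had an unadjusted p under 0.05. Il12a, Il10 and Cd86 were not tested. Il12a was well above background on only 1 array in each group and so did not meet the background rule. Its log2 ratios were 3.15 on array 1 and -2.56 on array 2, which favoured Cy3 on both arrays. Il10 was too dim, and Cd86 carried the non-uniformity flag on array 1.

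**Figure D2:**
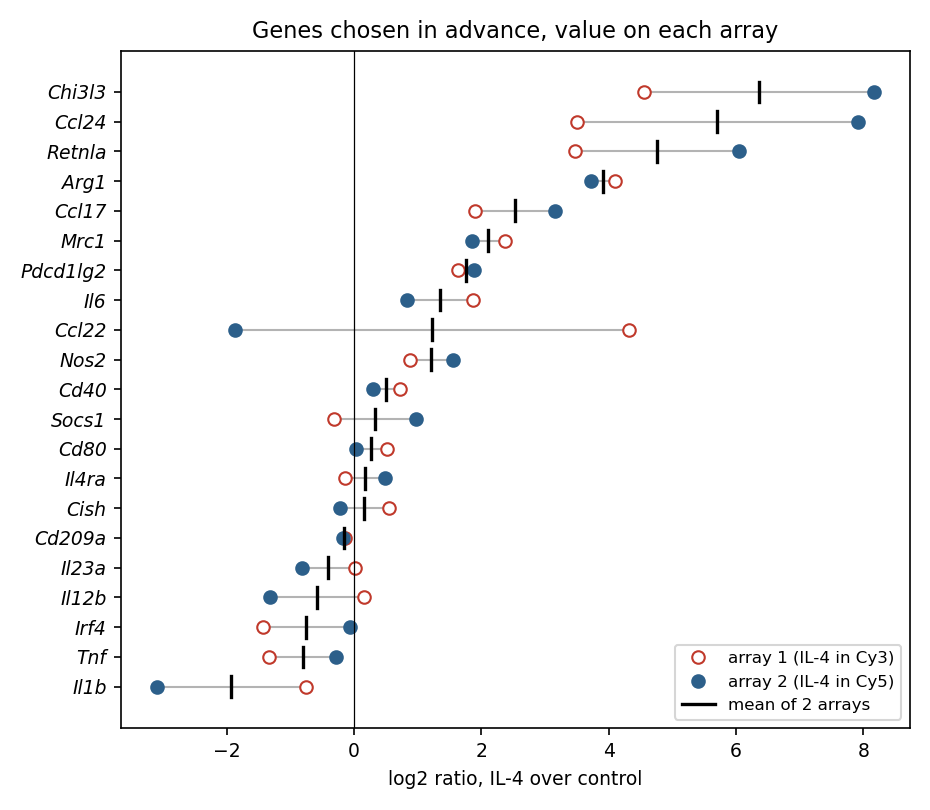
Log2 ratio of IL-4 over control moDCs for the 21 tested genes chosen in advance, on array 1 (open red circles), array 2 (filled blue circles) and as the mean of 2 arrays (black bars). Chi3l3, Ccl24, Retnla and Arg1 lie above 3 on both arrays, and Ccl22 lies on opposite sides of 0.

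Among the gene lists, camera with the preset correlation called 12 of 33, of which 4 were higher and 8 lower with IL-4. With an estimated correlation, and likewise with fry, 0 lists were called, the smallest adjusted p being 0.579 with an estimated correlation and 0.260 with fry, whose smallest unadjusted p was 0.0254. On simulated data, each of these tests recovered 0 of 100 shifted lists in this design, so their counts of 0 do not show that the lists were unchanged. In every list, 0 members passed limma's adjustment over all genes, and 130 of the 773 tested entries had an unadjusted p under 0.05. The counts of members below are therefore given as adjusted over the list alone.

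Alternative activation genes rose as a list (camera adjusted p = 4.22e-29; adjusted p = 0.579 with an estimated correlation). Their median log2 ratio was 1.29 over 33 tested genes, of which 22 were higher and 4 lower on both arrays, and 16 were at least 2-fold higher on both. When adjusted over the list alone, 15 members were higher and 0 lower, including Chi3l4, Ear11, Flt1 and Cd36. Ccl22 was the 1 member at least 2-fold in opposite directions. The chemokine list rose too (camera adjusted p = 3.53e-08; adjusted p = 0.579 with an estimated correlation), with a median of 0.29 and a mean of 1.00 over 29 genes, 14 higher and 4 lower on both arrays. The chemokine median was 0.72 on array 1 and 0.47 on array 2, 0.20 without the genes shared with the alternative activation list and 0.16 without the filter on dim probes. Of the chemokine genes, 8 were higher and 0 lower when adjusted over the list alone. The neutrophil attractant Cxcl5 had 3.19 ± 0.47, Ppbp 2.84 ± 0.93 and the monocyte attractant Ccl7 was at least 4.58-fold higher. Chemokine genes at least 2-fold higher on both arrays numbered 8, and 1, the fractalkine gene Cx3cl1 (-1.13 ± 0.14, named after its value was seen), was at least 2-fold lower.

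The list of arginine, polyamine and amino acid metabolism rose with a median of 0.67 over 24 genes (camera adjusted p = 9.32e-05; adjusted p = 0.579 with an estimated correlation), 11 higher and 6 lower on both arrays. Without the genes shared with the alternative activation list, its median was 0.39 over 22 genes (camera adjusted p = 0.0035). Single members, 1 higher and 1 lower, passed when adjusted over the list alone. Arg1 was the first, and Arg2, the mitochondrial arginase, was the second at -2.20 ± 0.41. Gatm, which makes the creatine precursor, had 2.10 ± 0.97, and Kmo, an enzyme of the kynurenine pathway, -1.48 ± 0.54. Hypoxia and stress response genes rose with a median of 0.44 over 30 genes (camera adjusted p = 0.0018; adjusted p = 0.579 with an estimated correlation). Of these, 10 were higher and 4 lower on both arrays and 16 had opposite signs, with medians of 0.59 on array 1 and 0.22 on array 2, and 0.27 with median centring. The stress transcription factor gene Atf3 had 1.85 ± 0.49, Srxn1 1.14 ± 0.12, Gadd45b 1.15 ± 0.26 and the heat shock gene Hspa1a 1.06 ± 0.06, with 0 members past the threshold adjusted over the list alone and 3 at an unadjusted limma p under 0.05.

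Cell cycle and mitosis genes fell as a list (camera adjusted p = 3.36e-05; adjusted p = 0.579 with an estimated correlation). Their median was -0.44 over 38 genes, of which 22 were lower and 3 higher on both arrays, with 0 at least 2-fold on both. In limma, 0 passed adjusted over the list alone and 2 had an unadjusted p under 0.05. Mki67, the proliferation marker, had -1.27 ± 0.52, E2f1 -1.10 ± 0.16 and Mcm7 -0.93 ± 0.72, while E2f2 had 1.24 ± 0.41. Genes of antigen presentation by MHC class II fell with a median of -0.48 over 21 genes (camera adjusted p = 0.0083; adjusted p = 0.579 with an estimated correlation), 11 lower and 4 higher on both arrays. The median was -0.19 on array 1 and -0.49 on array 2. H2-Oa and H2-Ob, which encode the class II modulator DO, had -1.36 ± 0.65 and -1.10 ± 0.51, and H2-Eb2 -1.20 ± 0.52. The protease gene Ctss had 1.04 ± 0.87. In limma, 0 members passed adjusted over the list alone and 2 had an unadjusted p under 0.05.

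Monocyte and macrophage markers fell as a list while holding members in both directions (median -0.38 over 36 genes; camera adjusted p = 0.0038; adjusted p = 0.579 with an estimated correlation). Of the markers, 4 were higher and 5 lower when adjusted over the list alone. Chi3l3 and the lipoprotein lipase gene Lpl (3.18 ± 1.19, other probe 2.61) were among the higher ones, and Ly6c1 and the fractalkine receptor gene Cx3cr1 (-3.04 ± 0.97) among the lower ones. The others were Mrc1 and F13a1 (1.83 ± 0.42) on the higher side and Sepp1 (-1.92 ± 0.48), Nr4a1 (-2.02 ± 0.88) and C5ar1 on the lower, of which F13a1, Sepp1 and Nr4a1 were named after their values were seen. Dendritic cell markers fell with a median of -0.22 over 28 genes (camera adjusted p = 0.0065; adjusted p = 0.579 with an estimated correlation), 13 lower and 5 higher on both arrays. The median was -0.28 on array 1, -0.15 on array 2 and -0.35 with median centring. Amica1 had -2.87 ± 0.73, the stem cell factor receptor gene Kit -1.94 ± 0.63 and the transcription factor gene Batf3 2.12 ± 1.04, with 0 members past the threshold adjusted over the list alone and 6 at an unadjusted limma p under 0.05. A rank-based camera ended this call, with an adjusted p of 0.0988. Chemokine receptors fell with a median of -0.30 over 20 genes (camera adjusted p = 0.0028; adjusted p = 0.579 with an estimated correlation). Of these, 8 were lower and 5 higher on both arrays and 7 had opposite signs. The receptor median was -0.39 on array 1 and -0.06 on array 2, -0.06 without the filter on dim probes and -0.18 with the strict filter. Adjusted over the list alone, 2 were lower, Fpr1 and Cx3cr1, and 0 higher. The complement receptor gene C5ar1 had -1.75 ± 0.35 and Ccr2 2.43 ± 1.97. The rank-based camera ended this call as well, with an adjusted p of 0.186.

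Genes of cholesterol and fatty acid synthesis and efflux fell with a median of -0.40 over 32 genes (camera adjusted p = 0.0028; adjusted p = 0.579 with an estimated correlation), 15 lower and 5 higher on both arrays, with medians of -0.17 on array 1 and -0.38 on array 2. In limma, 0 passed adjusted over the list alone and 3 had an unadjusted p under 0.05. Mylip, which degrades the LDL receptor, had -1.24 ± 0.43, whereas Lpl and the fatty acid binding protein gene Fabp4 (1.34 ± 1.22) were higher. Glycolysis genes fell with a median of -0.35 over 23 genes at the edge of the threshold (camera adjusted p = 0.0491; adjusted p = 0.653 with an estimated correlation), 9 lower and 3 higher on both arrays and 11 with opposite signs. Its median was -0.32 on array 1 and -0.11 on array 2. The aldolase gene Aldoc (-2.47 ± 0.15) was the 1 member lower when adjusted over the list alone, and 0 were higher. Hk3 had 1.29 ± 0.56, Pfkp 1.10 ± 0.79 and Eno2 0.86 ± 0.37. This call was lost under 4 of 10 processing settings, with medians of -0.23 for the mean of a gene's probes and -0.17 after removal of the trend with probe bases.

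**Figure D3:**
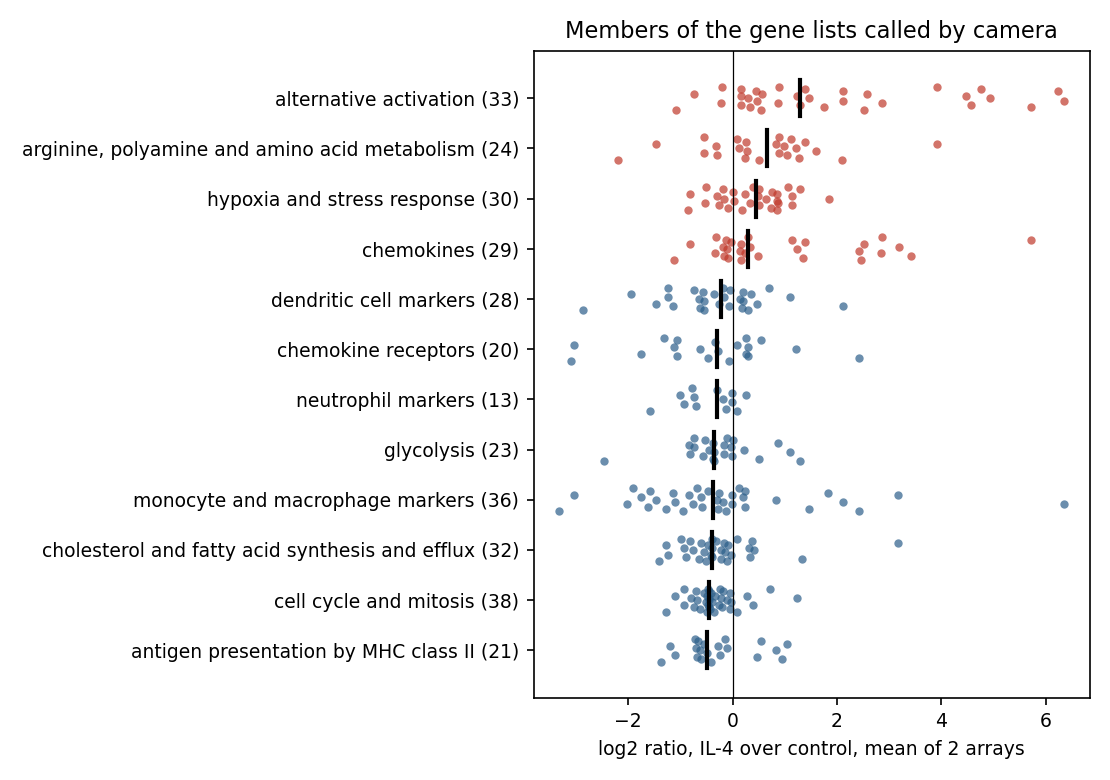
Mean log2 ratio of IL-4 over control moDCs (2 arrays) for each tested member of the 12 lists called by camera, with the number of members in brackets and the list median as a black bar. Red lists were called higher and blue lists lower, and the alternative activation list has the highest median, 1.29.

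Markers of neutrophils, a cell type outside the selection, fell as a list (median -0.31 over 13 of 19 genes; camera adjusted p = 0.0018; adjusted p = 0.579 with an estimated correlation). Of these, 7 were lower and 1 higher on both arrays, with medians of -0.63 on array 1 and -0.23 on array 2, and -0.10 without the filter on dim probes. In limma, 0 passed adjusted over the list alone and 1 had an unadjusted p under 0.05. Ly6g was at least 2.89-fold lower, Camp had -0.92 ± 0.26 (other probe -0.36), Lcn2 -1.01 ± 1.26 and Cebpe -0.74 ± 0.15. Ly6g belongs to the Ly6 family, whose sequences are alike, so its value is uncertain. Whether its probe tells it apart from the other Ly6 genes was not tested. The neutrophil list moved in the same direction as the monocyte, dendritic cell, chemokine receptor and cell cycle lists.

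Inflammatory and Th1-polarizing cytokine genes did not pass as a list (median -0.34 over 23 genes, camera adjusted p = 0.0766), with 9 lower and 3 higher on both arrays. Their median was -0.11 on array 1 and -0.50 on array 2. In limma, 0 passed adjusted over the list alone and 3 had an unadjusted p under 0.05. Il1b was lower, and Il6, Nos2 and the interferon gene Ifnb1 (1.06 ± 0.45) were higher. The list was called lower with the processed intensities (adjusted p = 0.0308), with the rank-based camera (0.0239) and after removal of the trend with probe bases (0.0226). Th2-polarizing and regulatory factors did not pass either (camera adjusted p = 0.729). Their median was 0.15, their mean 0.00 and the direction of the test downward, over 16 genes. On single arrays the median was negative, -0.12 on array 1 and -0.23 on array 2. Ccl17 and the retinoic acid enzyme gene Aldh1a2 (1.32 ± 0.36) were higher, and the co-stimulatory ligand gene Icosl (-1.76 ± 0.49) and the lectin gene Clec4a4 (-1.24 ± 0.19) lower. In limma, 0 members passed adjusted over the list alone and 6 had an unadjusted p under 0.05. Notch ligands and receptors had a median of -0.14 over 11 genes (camera adjusted p = 0.0749), where the Fringe genes Mfng and Lfng had -1.61 ± 0.96 (other Mfng probe -2.15) and -0.97 ± 0.18, Notch2 had -0.57 ± 0.34 and Rbpj had 0.70 ± 1.14. The Notch list was called lower in 4 of 10 other processing settings, with adjusted p-values from 0.0110 to 0.0492. Its median was -0.40 on array 1 and -0.35 on array 2. In limma, 0 Notch genes passed adjusted over the list alone and 1 had an unadjusted p under 0.05.

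Interferon-stimulated genes had a median of 0.09 over 49 genes, 13 higher and 13 lower on both arrays (camera adjusted p = 0.682). Ifitm3 had -1.69 ± 0.56, Oas2 -1.40 ± 0.13, Ly6e -2.15 ± 1.82 and Ifi27l2a -1.32 ± 0.39. Pattern recognition receptors had a median of -0.24 over 26 genes (camera adjusted p = 0.0689) and histone acetyltransferases and deacetylases -0.10 over 30 (0.180). Genes of MHC class I presentation (median 0.08, 23 genes), co-stimulatory and co-inhibitory ligands (-0.09, 21 genes), the NF-kappaB pathway (0.11, 25 genes) and the JAK-STAT pathway (0.01, 31 genes) each had a camera adjusted p of 0.851. The last 3 had a median whose sign differed from that of the test. Medians on arrays 1 and 2 were -0.48 and 0.03 for MHC class I presentation and 0.51 and 0.03 for the co-stimulatory and co-inhibitory ligands. They were 0.02 and -0.07 for the NF-kappaB pathway and -0.29 and 0.21 for the JAK-STAT pathway. In limma, 0 members of these 7 lists passed adjusted over the list alone and 10 had an unadjusted p under 0.05. The pattern recognition list was called lower in 4 of 10 other processing settings, with adjusted p-values from 0.0337 to 0.0492.

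Markers of other cells gave no call for T cells (median -0.08, 11 genes, camera adjusted p = 0.559), B cells (0.12, 8 genes, 0.545), NK cells (0.01, 9 genes, 0.682), plasmacytoid dendritic cells (-0.27, 11 genes, 0.401), the erythroid and platelet lines (0.06, 8 genes, 0.466) and stromal and endothelial cells (-0.17, 10 genes, 0.116). The mean and the test of the NK list were negative. The plasmacytoid median was -0.80 on array 1 and -0.003 on array 2. Medians of the B cell, NK cell, erythroid and platelet, and stromal lists had opposite signs on the 2 arrays. The stromal list was called lower in 2 of 10 other processing settings (adjusted p = 0.0356 and 0.0492). Of these markers, 1 of B cells, the signalling adaptor gene Blnk, and 1 of platelets, Ppbp, were higher when adjusted over the list alone. In limma, 0 members of the other 4 lists passed, and 5 had an unadjusted p under 0.05. Blnk was chosen after its value was seen. Markers of basophils, mast cells and eosinophils had a median of -0.02 over 8 genes (0.116). Of them, 2 were lower when adjusted over the list alone, Kit and the histamine-forming enzyme gene Hdc (-1.66 ± 0.10), while Siglec5 had 1.40 ± 0.79 (other probe 0.41) and Gata2 -0.95 ± 0.55.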

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

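The tests of probe bases, of probes of the same gene, of the dye orientation and of the glycolysis list were chosen only after the result was seen, as was the restriction of the test of shared members to lists that have any; the test of the neutrophil markers was chosen before.

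Of 35 control probes outside the comparison, 4 had a dye and array in which every spot was well above background. In the other 31, median signals were 1.01 to 1.85 times those of the negative controls, with a median of 1.22. The adenovirus E1A probe a107 had a median signal of 758 in Cy3 over 32 spots, against 81.8 for 153 negative-control spots, and 155 in Cy3 on array 2; in Cy5 it had 100.7 and 87.5 on the 2 arrays. Probe a22 had 139 in Cy5 on array 1, against 45.9, and its spots were well above background in both dyes on both arrays. Probe n9 had 327 in Cy3 on array 1 and 181 on array 2. The spike-in probe ERCC-00062, with 10 spots, had 231 in Cy3 on array 1 and 202 on array 2. The negative controls had 82.5 in Cy3 on array 2. The labels do not say whether spike-in RNA was added.

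The ratios of the 2 arrays had opposite signs for most genes once turned to IL-4 over control. A candidate explanation is dye bias of single probes. The difference between the arrays fell with the number of adenines in the probe (r = -0.484 across 18749 genes, 95% interval -0.495 to -0.473), and base counts explained 32.2% of its variance against 6.14% of that of the mean ratio. A real difference between the culture pairs is argued against as the whole cause by genes with several probes: over 3912 genes the difference correlated at r = 0.131 between probes (0.100 to 0.162) and the mean ratio at 0.677 (0.660 to 0.694). A wrong dye label on 1 array is argued against because 16 alternative activation genes were at least 2-fold in the same direction on both arrays and 1 in opposite directions; a smaller difference between the cultures stays open.

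Lower neutrophil markers with IL-4 could reflect fewer neutrophils in those cultures, although the CD11c selection would remove most of them. Of the 13 tested markers, 53.8% (7) were lower on both arrays. Among the most abundant neutrophil transcripts, S100a8 had a log2 ratio of -0.78 ± 0.72 and S100a9 0.04 and -0.04 on arrays 1 and 2. The markers tested are the 13 of 19 bright enough in either kind of cell, and monocytes also express S100a8 and S100a9, so fewer neutrophils and lower expression in the moDCs cannot be told apart.

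The 12 called lists might follow from the bases of their probes or from members shared with the alternative activation list. With each array's trend with probe bases removed, 91.7% (11 of 12) kept direction and call, which argues against probe bases for those 11. The glycolysis list had a median of -0.35 before and -0.17 after (adjusted p = 0.101), and it also lost its call in 3 settings that leave the trend in place, so for this list probe bases stay open. Without the alternative activation genes, 100% (4 of 4) of the called lists that hold some kept their call. This argues against members shared with the alternative activation list as the whole cause for chemokines and arginine metabolism. For the monocyte and dendritic cell lists, both called lower, the kept call is no test. The genes left out there were Chi3l3 and Mrc1 (6.36 and 2.11), and Batf3 and Irf4 (2.12 and -0.75). All but Irf4 were higher, so leaving them out works towards a lower call. The other 7 lists hold none of the alternative activation genes. Sharing among the other called lists was not tested. For example, Cx3cr1, C5ar1 and Ccr2 are in both the monocyte and the chemokine receptor lists, so those 2 calls are not independent. An effect of IL-4 on these lists remains a hypothesis, since the labels do not say whether the arrays hold separate cultures.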

How the results depend on the processing

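The removal of the trend with probe bases was chosen only after the result was seen, and the exclusion of alternative activation genes was added after the data were seen. The 0 genes called in each direction by limma became 1 higher (Rbp4) with the processed intensities and 3 higher with median centring. The separate-channel fit with a dye term had 4 higher. Its intraspot correlation could not be estimated and was set to 0, and its residual does not measure the spread of the ratio. Without the trend with probe bases, limma called 12 higher and 1 lower (Ly6i). The 12 were Arg1, Bex6, Cd36, Chi3l4, Chst7, Ear2, Ear10, Ear11, Ear12, Flt1, Gm6522 and Rbp4; Gm6522 is a Gm name, which the naming rule leaves out, and is given here because it passed. In the other 7 of the 10 processing settings, limma called 0 genes, with 462 to 875 genes at an unadjusted p under 0.05. Genes at least 2-fold higher on both arrays numbered 182, but 301 with the processed intensities and 102 with median centring; those lower numbered 242, but 388 with the processed intensities. Of the 301 and 388, 166 and 227 were also in the main counts, and of the 102, 90 were. At 1.5-fold the counts were 431 higher and 551 lower, below the 614 and 725 expected if the arrays were independent. At 3-fold they were 84 and 72, above the 12.4 and 8.39 expected. A single array gave 878 to 2456 genes at least 2-fold higher and 1456 to 1724 lower. The correlation between arrays was -0.270 with the processed intensities, -0.403 with median centring, -0.268 with the mean of a gene's probes and -0.125 without the trend with probe bases. With an estimated correlation, and with fry, 0 lists were called higher and 0 lower. The means of Il4ra and Cish turned to -0.016 and -0.022 with median centring. For these differences the cause was not tested. A single array gives neither a test nor a correlation.

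Of the 12 called lists, 11 kept direction and call in all 10 processing settings. The glycolysis list kept its call in 6, with adjusted p-values from 0.00911 to 0.101, and lost it with the processed intensities, the strict filter, the mean of a gene's probes and the trend removed. Of 462 values for 33 lists, 418 kept their side of the threshold, 30 lost a call, 14 gained one and 0 reversed. Of 1077 values for 108 named genes, 1059 kept direction and side, 16 gained a call and 2 reversed. On single arrays, 39 of 66 list medians lay within the spread between arrays and 27 did not. That spread comes from the same 2 arrays, so these counts cannot show whether a list is stable between arrays. Signal over background limits the dim genes: 39.7% of probes did not meet the background rule.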

Other observations

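The gene families here were chosen after their values were seen, and the lists before the data were examined.

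Of 11 families of related genes examined, 4 had a median log2 ratio beyond 1 or -1. Of 6 tested Ear ribonuclease genes, 5 were at least 2-fold higher on both arrays and 1 was lower on both, with a family median log2 ratio of 4.07 that ranged from 2.70 to 4.62 over 10 other processing settings. Of 8 Ly6 genes, 4 were at least 2-fold lower on both arrays (median -1.86, from -2.86 to -1.74 over the settings), and all 3 Pilr genes were (median -3.16, from -3.45 to -3.10). Of 5 Ifitm genes, which encode membrane proteins that restrict virus entry, 2 were at least 2-fold lower on both arrays (median -1.09, from -1.25 to -0.78). Members of the Ear, Ly6 and Pilr families resemble each other, and whether their probes tell them apart was not tested. The probes of Ear2 and Ear12 lie close together on chromosome 14, so the counts of Ear genes may hold the same gene more than once. The other 7 families had medians from -0.15 to 0.42. The Ms4a genes (11 tested) had 2 higher and 4 lower on both arrays and a median of -0.15, and the Hsp genes (23 tested) had 7 higher and 1 lower and a median of 0.36. The Clec4 (median 0.42), Cyp (-0.12), ribosomal protein (0.04), Slc7 (0.13) and Itga and Itgb (-0.09) families had medians whose sign turned in at least 1 of the 10 settings.

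Eicosanoid genes were not called as a list (median 0.06, mean -0.24, test downward, 22 genes, camera adjusted p = 0.171). Of its members, 2 were lower when adjusted over the list alone with limma, both of leukotriene synthesis: Alox5, the 5-lipoxygenase gene, had -2.84 ± 0.44 and Ltc4s, the leukotriene C4 synthase gene, -2.29 ± 0.47. The prostaglandin receptor gene Ptger2 had 2.22 ± 1.46 and Ggt5 -1.45 ± 0.05, with -0.10 from its other probe and an IL-4 signal well above background on 1 array. Lysosome and phagocytosis genes were not called (median -0.15, mean 0.11, test downward, 41 genes, adjusted p = 0.851). Of them, 3 were higher when adjusted over the list alone: Cd36, the proton pump subunit gene Atp6v0d2 (3.50 ± 1.00) and the cathepsin K gene Ctsk (2.55 ± 0.37). Genes of mitochondrial respiration and fatty acid oxidation had a median of 0.16 over 30 genes (adjusted p = 0.274), and 1 member, the nuclear receptor gene Pparg (2.86 ± 0.58), was higher when adjusted over the list alone. Matrix metalloproteases and adhesion genes had a median of 0.01 over 33 genes (adjusted p = 0.851). Vcam1 was the 1 member higher when adjusted over the list alone, Timp1 had 1.85 ± 0.11, and the thrombospondin gene Thbs1 and the integrin gene Itgb5 had -2.31 ± 0.37 and -2.07 ± 0.65.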
